A study of Streptomyces filamentosus with 2 samples.

How the data were processed

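RNA was measured by sequencing in 2 libraries of Streptomyces roseosporus MT19, a filamentous soil bacterium that makes the lipopeptide antibiotic daptomycin and that GEO lists under the name Streptomyces filamentosus. One library came from the wild-type strain and 1 from a strain with the dhyR gene deleted. Per the labels' protocols, both strains were grown in fermentation medium with shaking, total RNA was depleted of ribosomal RNA with a Ribo-Zero kit, and libraries were made with a kit that keeps the strand of the RNA. The submitters' processing notes name Trimmomatic for read trimming and give the genome build as mm10, which is the name of a mouse assembly and does not match the bacterial locus tags of the rows. The aligner, the counting tool, its strand setting and the bacterial assembly are not given in the sources used here.

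The authors deposited raw counts of reads for each row of a table of 6764 rows. The rows are locus tags of the annotation, transcripts that the authors predicted antisense to an annotated gene, and other transcripts that they predicted outside such positions. The counts are whole numbers and were used as deposited. The authors also deposited 1 table per library whose file name says RPKM, here treated as a score because its values are whole numbers. For rows whose length follows from the deposited coordinates, these values matched the count divided by the length and by a library denominator, with the decimals dropped, in 42 of 49 rows of the wild type and 38 of 50 rows of the deletion. The other 7 and 12 rows did not match, and the definition of the denominator is not given in the sources used here. The denominators found in this way were 8031910 reads for the wild type and 7969651 for the deletion. Per the file headers, a further deposited table gives the start, end and strand of 27 antisense transcripts, names the gene each overlaps and gives the position and strand of 23 of these genes, with no chromosome name or build.

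The tables give locus tags and no gene names, products or genome sequence, and no annotation was used here. The row of dhyR was therefore not looked up, so the check that the deleted gene is silent in the deletion library was not made, and no row was named from its values. The daptomycin cluster and the other fixed lists, 34 lists chosen by symbol or product, were not analysed for the same reason. All per-sample columns were mapped to a sample.

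In the table, 4 locus tags appeared on 2 rows each with identical values and were kept once, which left 6760 rows. Library totals over these rows were 7407689 reads for the wild type and 6613215 for the deletion. The ratio of deletion over wild type was computed after scaling by the trimmed mean of M-values (TMM, edgeR 4.0.16 in R 4.3.3) with 0.5 reads added to each library. Each ratio has an exact 95% interval from the binomial distribution of the reads between the libraries. Reads are not independent molecules, so intervals and floors cover counting error only. A count of 0 allows up to 3 reads, which is a CPM of 0.405 in the wild type and 0.454 in the deletion.

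With 1 library per genotype there is no replicate, no error between cultures and no test across genes. A row was counted as higher or lower when its ratio was at least 2-fold, its counting interval excluded 1 and both libraries together held at least 20 reads. For a class of rows, the median log2 ratio was ranked among the medians of 10000 random lists of the same size, matched on abundance in 10 groups. These ranks describe the 2 libraries. The rule for naming features, fixed before the data were examined, took dhyR, the daptomycin genes, the 12 largest differences per direction among rows with a name and at least 100 reads in the higher library, and the leading members of each list, and fell back to at most 2 identifiers per direction where rows cannot be named. That fallback applied to the locus tags. Predicted transcripts named below were chosen after their values were seen.

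The steps were tested on simulated data drawn from the means and totals of this comparison, with 6760 rows of which 200 were changed and the dominant transcript kept its observed ratio. With counting noise alone, 100% of rows raised 4-fold, 100% of rows lowered 4-fold, 100% of rows raised 3-fold and 96% of rows lowered 3-fold were recovered, and 27 and 13 of 6559 unchanged rows were counted as higher and lower. With an assumed dispersion of 0.1 between libraries, recovery was 96% and 92% at 4-fold and 80% in both directions at 3-fold, and 374 and 390 unchanged rows were counted as higher and lower. The simulated changes were placed in better-covered rows only, and recovery was not split by abundance. These shares therefore do not give the recovery of rows near the read minimum, which was not simulated.

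Row lengths were implied from counts and deposited RPKM where the RPKM was at least 20, which gave a length to 2824 rows. Against 43 rows of known length the largest error was 1.28%. The denominators had been fitted to these same rows, so this was no independent check. None of them was a predicted non-antisense transcript, so the error of implied lengths in that class is not known. There, Predicted_non_antisense_transcript-94 had 0 wild-type reads but a wild-type RPKM of 4, which a count divided by length and denominator cannot give. The numbers in the locus tags of the main series were used as an order along the chromosome, and rows with tags of other series were left out of that step. Alternatives were total reads, median of ratios (DESeq2 1.42.0), upper-quartile scaling, totals without the 10 most abundant rows, the deposited RPKM, 5 reads added, other read minimums, other interval rules and thinning. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used.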

Results

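The transcriptome of S. roseosporus MT19 was compared with that of a strain lacking dhyR, a gene for a transcriptional regulator that the series title connects with daptomycin biosynthesis. The comparison asks which transcripts differ in amount when the regulator is missing. Each genotype had 1 library, so every difference given here is a difference between 2 libraries without a replicate check, and its interval covers counting error only. The wild-type library held 7407689 reads over 6760 rows and the deletion library 6613215. Of these rows, 6627 were annotated locus tags, 27 were predicted antisense transcripts and 106 were predicted transcripts of other positions, called non-antisense here. A total of 131 rows had no read in either library.

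By share of reads, the largest difference between the libraries was in 1 unannotated RNA. Predicted_non_antisense_transcript-96 took 4475467 reads in the wild type, which was 60.4% of the library (exact Clopper-Pearson 95% interval 60.38% to 60.45%). In the dhyR deletion it took 747739 reads, or 11.3% of the library (interval 11.28% to 11.33%). Its length, implied from the deposited counts and RPKM, was 252 bases. After TMM scaling it was 12.2-fold lower in the deletion, a log2 ratio of -3.61 (counting interval -3.62 to -3.61). On total reads, without TMM, the log2 ratio was -2.42, in the same direction. Predicted_non_antisense_transcript-98, with an implied length of 227 bases, was also far lower, at 21548 reads in the wild type and 3319 in the deletion (log2 ratio -3.73, counting interval -3.78 to -3.68). Annotated genes accordingly held 37.8% of the wild-type reads and 86.3% of the deletion reads, so the wild type was sequenced to 2799449 annotated reads and the deletion to 5709341.

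**Figure D1:**
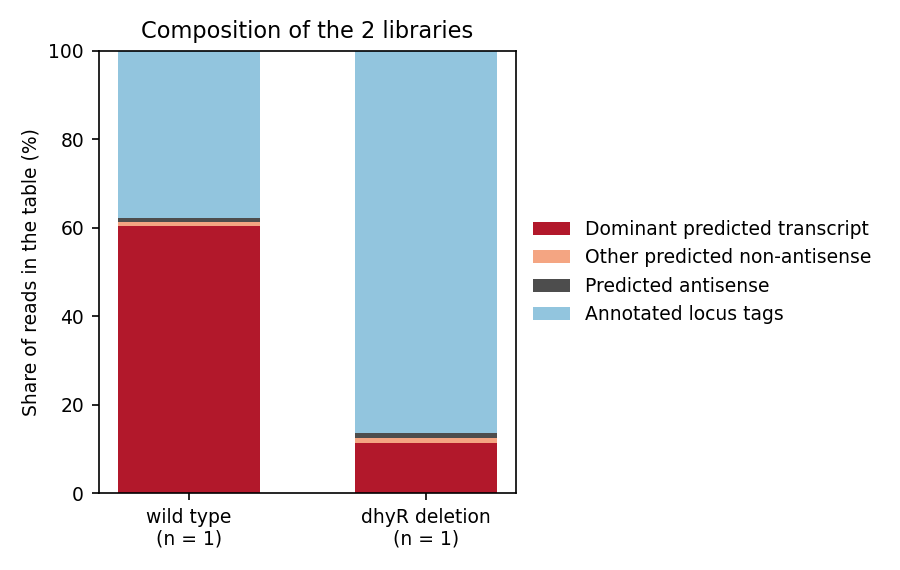
Share of the reads in the table (%) taken by the dominant predicted transcript, other predicted non-antisense transcripts, predicted antisense transcripts and annotated locus tags, in 1 wild-type and 1 dhyR deletion library. The dominant transcript takes 60.4% of the wild-type bar and 11.3% of the deletion bar.

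This composition set the scale of every other ratio. On total reads the median row with at least 20 reads had a log2 ratio of 1.18, so the typical transcript was 2.26-fold higher in the deletion. After TMM scaling the median was -0.02. The shift between the scalings was 1.20 on the log2 scale for every row, and the ratios below are TMM-scaled, relative to the typical row.

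Among the 5206 rows with at least 20 reads, 585 were at least 2-fold higher in the dhyR deletion and 722 at least 2-fold lower, and 3899 were neither. Differences of at least 4-fold were found in 114 rows that were higher and 139 that were lower. Higher rows made up 44.8% of the counted rows. On total reads the counts were 2917 higher and 91 lower, with 97.0% higher, and with the deposited RPKM they were 2640 and 134, with 95.2% higher. Of the 722 rows that were lower after TMM scaling, 91 were also lower on total reads. In simulated libraries with a dispersion of 0.1, unchanged rows alone gave 374 higher and 390 lower at 2-fold and 30 and 15 at 4-fold, so differences of this size arise in the absence of change at that dispersion, which was assumed and not measured here.

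**Figure D2:**
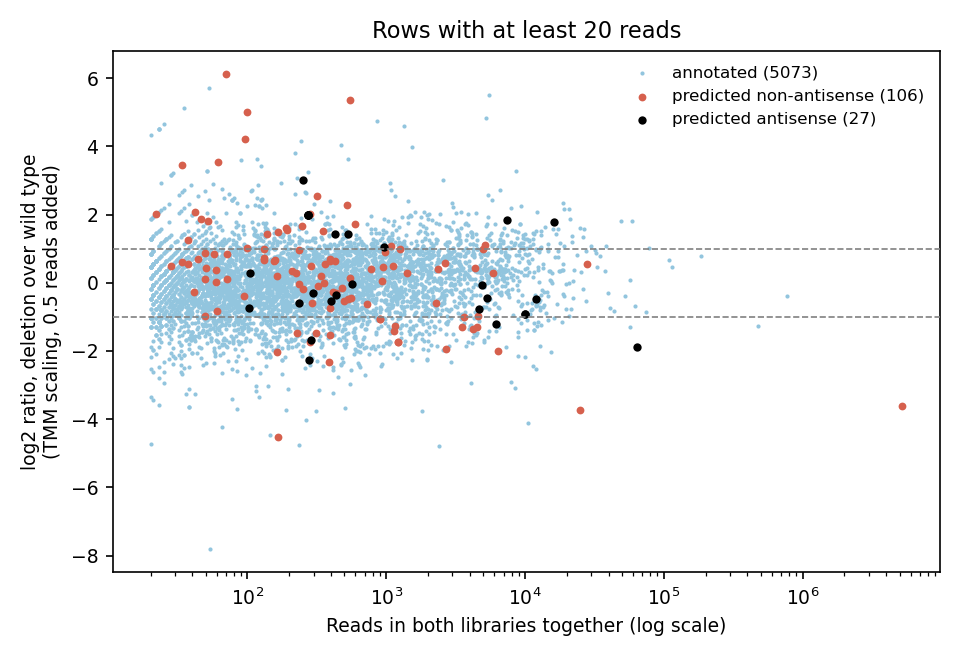
TMM-scaled log2 ratio of deletion over wild type against the reads of both libraries together (log scale) for 5206 rows with at least 20 reads, coloured by class, with dashed lines at a 2-fold difference. The dominant predicted transcript lies alone at the right, at a log2 ratio of -3.61.

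Annotated genes were divided between both directions. Of 5073 measured annotated rows, 550 (10.8%) were higher and 697 (13.7%) lower in the deletion, and 3826 were neither. SSIG_RS01345 was the most strongly higher annotated row with at least 100 reads in 1 library. It had 58 reads in the wild type and 5439 in the deletion, which was 45.5-fold higher (log2 ratio 5.51, counting interval 5.15 to 5.92). SSIG_RS07850 followed with 89 and 5183 reads, 28.3-fold higher (log2 ratio 4.82, counting interval 4.53 to 5.15). SSIG_RS0232470 was the most strongly lower, with 2221 reads in the wild type and 164 in the deletion, 27.6-fold lower (log2 ratio -4.79, counting interval -5.03 to -4.56). SSIG_RS04380 had 219 and 16 reads, 27.2-fold lower (log2 ratio -4.77, counting interval -5.64 to -4.07). On total reads, which raises every ratio alike, SSIG_RS0232470 and SSIG_RS04380 were still lower, with log2 ratios of -3.59 and -3.57. The functions of these loci are not given in the files.

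Of the 4 named loci, SSIG_RS01345, SSIG_RS07850 and SSIG_RS04380 each stood first in a run of neighbouring tags that differed in the same direction. SSIG_RS0232470 carries a tag of another number series and was not placed. Most locus tags are numbered along the chromosome: over 18 of the 23 listed partner genes with deposited coordinates, tag number and position had a Spearman correlation of -1 across genes. The other 5 carry tags of other series that break this order. Such tags were left out here, 266 of the measured annotated rows, which left 4807, so a neighbour in tag order can have an unplaced gene in between. SSIG_RS01345 was the first of 4 consecutive measured tags that were all higher in the deletion, with 91 reads together in the wild type and 6859 in the deletion and a median log2 ratio of 4.39. Of these reads, 58 and 5439 were those of SSIG_RS01345 alone. The 3 measured tags just before it were all lower, with 7450 and 5591 reads and a median of -1.43, which was -0.24 on total reads with no tag 2-fold lower. SSIG_RS07850 was the first of 5 higher tags with 125 and 5700 reads, of which it held 89 and 5183 itself, and a median of 2.73. A run of 4 lower tags lay close behind it in tag order, with 811 and 536 reads and a median of -2.60. SSIG_RS04380 was the first of 4 lower tags with 685 and 176 reads and a median of -3.27. In all, 13 runs of 4 or more tags were higher and 20 were lower, 33 together, against a median of 2 and a highest of 9 in 1000 shuffles of the same rows. On total reads, 230 runs of 2-fold higher tags and 1 of 2-fold lower tags were found. The median of each of the 20 lower runs was below 0 on total reads. These rows were picked as at least 2-fold lower after TMM scaling, which keeps them from lying far above 0 on total reads. The sign of these medians is therefore no further support for the lower runs.

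**Figure D3:**
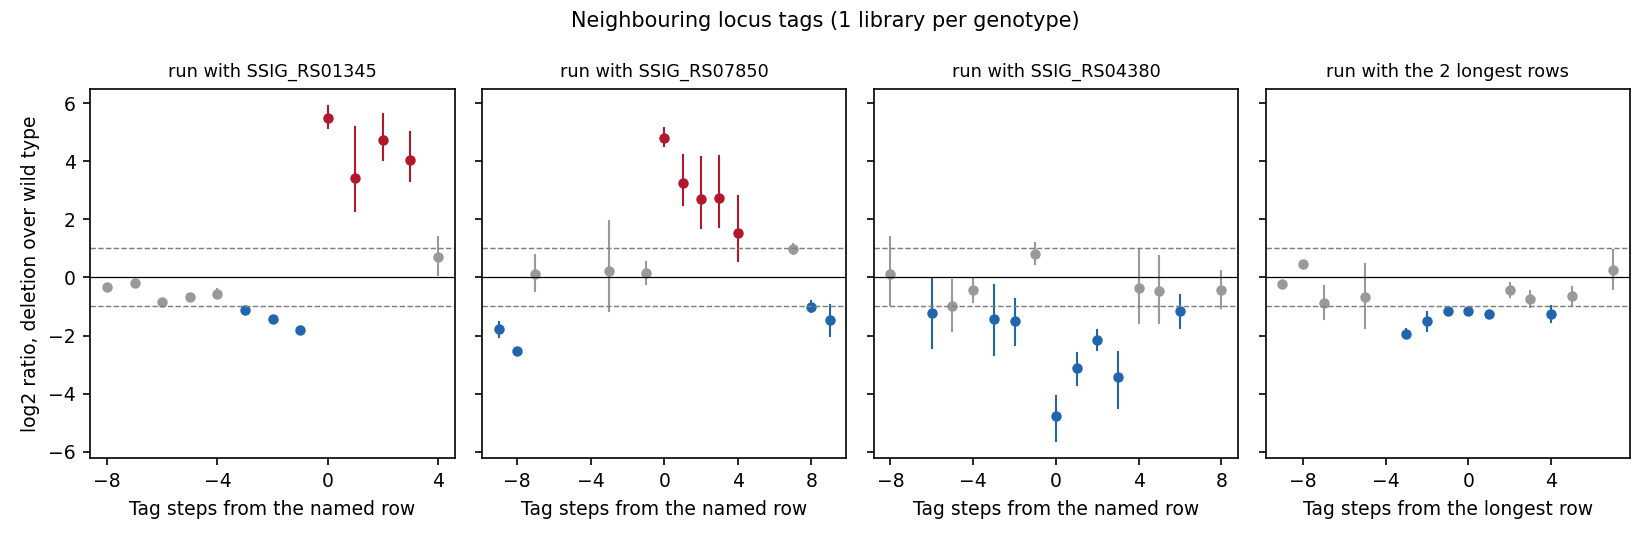
TMM-scaled log2 ratio of deletion over wild type with its 95% counting interval, by tag order (1 step is a difference of 5 in tag number). Rows of at least 20 reads are shown around 3 named locus tags and around the row with the longest implied length. Red points are at least 2-fold higher and blue points at least 2-fold lower; 4 red points begin at SSIG_RS01345 and 5 at SSIG_RS07850.

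Predicted non-antisense transcripts differed in both directions, with a median above that of all rows. Of 106 measured transcripts, 25 (23.6%) were higher, 21 (19.8%) were lower and 60 were neither, against 11.2% higher and 13.9% lower among all rows. Their median log2 ratio was 0.40, above each of 10000 random lists matched on abundance, of which 95% lay between -0.24 and 0.20. With transcripts of identical counts kept once, the median over 104 was 0.43. The most strongly higher of those with at least 100 reads in 1 library was Predicted_non_antisense_transcript-95, with 6 reads in the wild type and 545 in the deletion (log2 ratio 5.36, counting interval 4.34 to 6.93). The most strongly lower was Predicted_non_antisense_transcript-18, with 152 and 13 reads (log2 ratio -4.53, counting interval -5.52 to -3.76). On total reads the class median was 1.60 against 1.18 for all rows, and 71 were higher and 4 lower. The files do not say from which library the transcripts were predicted. Each predicted transcript, antisense or not, had a deposited RPKM of at least 176 in at least 1 library. More of them fell below this value in the wild type than in the deletion. The random lists had no such limit, so the ranks and shares of the predicted classes cannot be separated from this selection.

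The 27 predicted antisense transcripts were 39 to 723 bases long, with 20 on the plus strand and 7 on the minus strand. The authors' list classed 9 as convergent with the overlapped gene, 5 as divergent and 9 as enclosed, and gave no class for 4. In the deletion 10 were higher, 4 were lower and 13 were neither, and on total reads 13 were higher and 1 was lower. Their median log2 ratio was -0.29, at percentile 5.62 of the matched random lists. Several transcripts had identical counts. The 4 transcripts of 151 bases numbered 5, 10, 21 and 24 each had 30 reads in the wild type and 245 in the deletion, and the pair numbered 1 and 27, at opposite ends of the coordinates, each had 4828 and 5232. With identical rows kept once, 7 were higher, 4 lower and 12 neither, and the median of -0.37 lay inside the random range of -0.38 to 0.54.

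Antisense RNA and the overlapped gene differed in opposite directions at 1 locus, and at others 1 member alone or both strands differed. Predicted_antisense_transcript-25, at positions 7536892 to 7537043 on the plus strand and inside a gene at 7535427 to 7537046 on the minus strand, had 14 reads in the wild type and 237 in the deletion (8.01-fold higher, counting interval on the log2 scale 2.27 to 3.94). The gene it lies in had 1328 and 768 reads (log2 ratio -1.82, counting interval -1.95 to -1.69), and its locus tag directly precedes SSIG_RS01345. Predicted_antisense_transcript-18, at 4258583 to 4259117, was the most abundant, with 41214 reads in the wild type and 22985 in the deletion (log2 ratio -1.87, counting interval -1.90 to -1.85). Its sense gene had 97 and 205 reads (log2 ratio 0.04, counting interval -0.31 to 0.41). At Predicted_antisense_transcript-22, 5859125 to 5859527, both strands were higher: the antisense RNA had 2028 and 14191 reads (log2 ratio 1.77) and the gene 6055 and 43403 (log2 ratio 1.81). On total reads transcript 18, at -0.68, and the gene of transcript 25, at -0.63, were no longer 2-fold lower, so the 2-fold call of opposite directions rests on TMM scaling. Transcript 25 itself was at 4.20 on total reads, so its sign stayed opposite to that of its gene. The build of these coordinates is not given in the sources used here.

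Across the 23 distinct pairs, the log2 ratios of antisense and sense had Pearson's r of 0.08 and Spearman's rho of 0.18, at percentiles 64.3 and 79.6 of 10000 random pairings. Without the 2 antisense transcripts farthest from the median, r was 0.40. Both members were higher in 1 pair, both were lower in 1 and they were opposite in 1, while 8 pairs had a difference in the antisense transcript alone, 3 in the gene alone and 9 in neither. In the pair with both lower, Predicted_antisense_transcript-3 had 0.0127 of the reads of its gene in the wild type and 0.0132 in the deletion. Its reads thus stayed a small, nearly constant fraction of those of the gene. In the pair with both higher, Predicted_antisense_transcript-22 had 0.335 of the reads of its gene in the wild type and 0.327 in the deletion, also nearly constant. Antisense reads exceeded those of the gene in 10 pairs in the wild type and in 8 in the deletion. Some pairs overlapped little, transcript 4 by 6 bases and transcript 17 by 20 bases. These pairs are loci within 1 comparison and are not independent replicates.

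**Figure D4:**
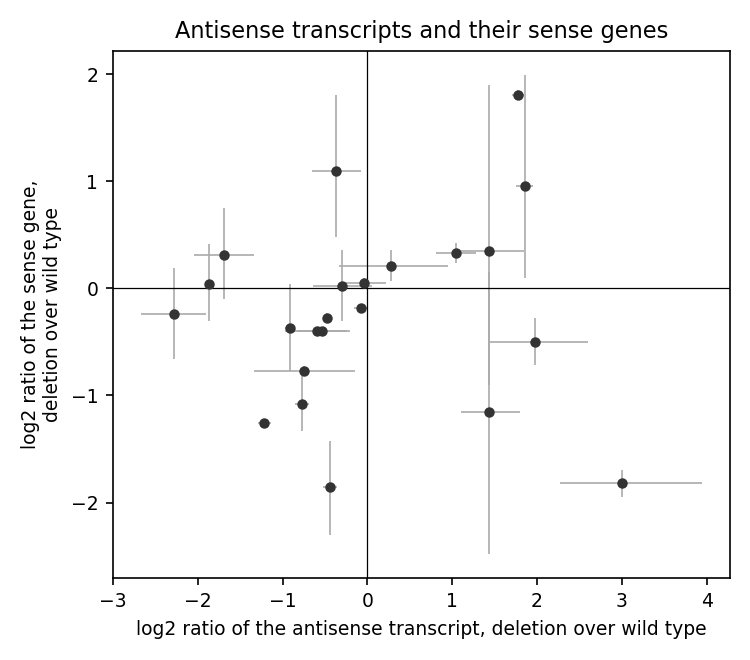
TMM-scaled log2 ratio of deletion over wild type for the gene overlapped (vertical axis) against that of each of 23 distinct antisense transcripts (horizontal axis), with 95% counting intervals. The point at the lower right is Predicted_antisense_transcript-25, 8.01-fold higher, whose gene is at a log2 ratio of -1.82.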

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

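The deposited RPKM imply library denominators larger than the counted reads, an excess that none of the comparisons examined. The excess was 7.76% of the denominator in the wild type and 17.0% in the dhyR deletion, and the share in the deletion was above that in the wild type. The denominators were fitted to the RPKM of rows with known length and did not match 7 of 49 rows of the wild type and 12 of 50 of the deletion. How the authors defined them is not given in the sources used here, so it stays open whether the excess stands for reads outside the rows, and with 1 library per genotype the difference has no replicate check.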

How the results depend on the processing

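The alternatives were chosen before the data were examined, except keeping identical rows once and the thinning without the dominant transcript. The counts of higher and lower rows depended on the scaling: 585 and 722 with TMM became 2917 and 91 on total reads and 2640 and 134 with the deposited RPKM. They were 356 and 353 with at least 200 reads and 300 and 379 when the interval had to exclude a 2-fold difference, both of which count fewer rows by construction. Under the other 9 alternatives (median of ratios, upper quartile, totals without the 10 most abundant rows, 5 reads added, no minimum, no interval rule, thinning of the wild type, and the 2 added later) they stayed between 477 and 703 higher and between 635 and 847 lower. With upper-quartile scaling the balance turned, with 703 higher and 635 lower (52.5% higher), so which direction was larger depended on the scaling. The 4 named locus tags and the dominant transcript had 30 values from the 4 other scalings, the RPKM and 5 added reads, of which 13 lay outside the counting interval of the main value. None changed sign, which the scaling fixes for the higher rows on total reads. The 14 antisense transcripts counted as changed were all at least 100 bases long. The fixed gene lists, the daptomycin cluster median and the removal of rRNA and tRNA rows were not run, since the rows carry no names. No paired analysis was possible because each genotype has 1 library, and leaving out a replicate was not possible either. Depth limited the wild type more than its total shows: without the dominant transcript it held 2932222 reads against 5865476 in the deletion.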

Other observations

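The 2 longest rows of the table lay side by side and were lower in the deletion after TMM scaling. Among rows with an implied length, the 2 longest, of 21.8 kb and 17.5 kb, and the fourth longest, of 7.05 kb, had consecutive locus tags and belonged to a run of 5 lower tags with a median log2 ratio of -1.27. The row of 21.8 kb had 6033 reads in the wild type and 5486 in the deletion (log2 ratio -1.17, counting interval -1.22 to -1.12). The row of 17.5 kb had 9641 and 8797 (log2 ratio -1.16, counting interval -1.21 to -1.12), and that of 7.05 kb had 2179 and 1849 (log2 ratio -1.27, counting interval -1.36 to -1.18). On total reads these differences vanished, with log2 ratios of 0.03, 0.03 and -0.07, so their direction rests on the correction for the dominant transcript. The third longest row by implied length, of 7.30 kb and outside this run, was higher, with 632 and 2471 reads (log2 ratio 0.93, counting interval 0.81 to 1.06). It and the other 3 rows with an implied length of at least 5 kb were not at least 2-fold different. These rows were chosen after their values were seen, and the files give no names for them.

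Only 1 row with at least 20 reads in the wild type had no read in the deletion. SSIG_RS29440 had 54 wild-type reads, which corresponds to 110 reads in the deletion at an equal level. Set against a floor of 3 reads, it was 36.8-fold lower, or 16.1-fold on total reads. Its exact counting interval, which includes the error of the wild-type reads, ended at 28.9-fold lower. It was chosen after its values were seen, and the files do not pair it with a gene name. In the opposite direction, 8 rows had no wild-type read and at least 20 reads in the deletion. Rows with at least 1000 reads had a median log2 ratio of 0.29 and those with 20 to 50 reads a median of -0.18. A total of 16 rows with at least 1000 reads shared both counts with another row, in 8 sets.

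The tests in the following paragraphs on the composition of the libraries and on the scaling and length of the dominant transcript were chosen after the results were seen. Most rows were higher per total read in the deletion, with a median log2 ratio of 1.18. Noise of rows with few reads is argued against, since rows with at least 200 reads had a median of 1.30. The weight of 1 transcript in the wild-type library may account for the shift: without it the median on total reads was 0.014.

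The dominant transcript itself was lower in the deletion. Scaling is argued against as the whole cause, because its highest log2 ratio over the scalings tried, -2.42, was still below -1. Whether short RNA was lost in general from the deletion library could not be decided. The other 106 predicted transcripts with an implied length under 300 bases, identical rows once, had a median log2 ratio of 0.38 (bootstrap interval 0.09 to 0.61). Of these, 29 were higher and 17 lower, among the latter Predicted_non_antisense_transcript-98 and Predicted_non_antisense_transcript-18. Each predicted transcript had a deposited RPKM of at least 176 in at least 1 library. More of them fell below this value in the wild type than in the deletion. Such a selection favours higher ratios, so no conclusion is drawn from this median. Whether the deletion of dhyR or a difference between single cultures or RNA preparations lowered the dominant transcript cannot be told apart with 1 library per genotype.

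Rows with adjacent locus tags differed together, with a correlation of 0.35 across neighbouring genes against a highest of 0.05 in 1000 shuffles. Copies with identical counts are argued against, since the correlation was 0.36 (bootstrap interval 0.32 to 0.40) without such rows of at least 100 reads. Neighbouring rows that share only part of their reads were not removed, so this does not cover them. A regional trend over long stretches is argued against as the source of a correlation of this size, which was 0.016 (interval -0.02 to 0.05) at 20 tags apart. Medians over 20 bins of tag order ran from -0.36 to 0.26, so weaker regional differences are not excluded. The correlation of adjacent tags exceeded that at 5 tags apart by 0.30, which is consistent with co-transcription of neighbouring genes. This remains a hypothesis, because strands and operons of the rows were not used here.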
